A study of Mus musculus and Homo sapiens with 36 samples.

How the data were processed

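The deposited table held whole-number counts per gene for 25209 genes of the mm9 refGene annotation, made with featureCounts 2.0.1 in paired-end mode over exons and without strand, per the file headers. The submitters' processing notes name featureCounts 2.0.0 instead, and also Trim Galore 0.6.4, Bowtie2 2.3.5.1, GATK 4.1.4.0, bedtools 2.92.2 and the mm9 build. Nothing in the sources used here says how reads that matched several places were treated. Genes that share sequence with others are therefore uncertain, among them Rprl3, Rpl37rt, Rpl32l, Eno1b, Pin1rt1, Gm4832, Gm20594, Mir6236, Lars2 and single histone genes. The counts carry no strand, so overlapping and antisense genes such as Mid1 and G530011O06Rik cannot be told apart by their shared reads.

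Of 36 samples in the labels, 32 had a column in the table and entered the comparisons. The 2 single-stranded DNA libraries and the 2 libraries of 30 min at 16 °C were not analysed here. Groups and replicate numbers came from the sample titles, 2 libraries per group in each of 16 groups. For Tn5 the titles give ng, as used here, while the column headers add a microlitre sign after ng. The Tn5 values may therefore be concentrations. No pair of replicates agreed within sampling noise, so each counted as 1 library (chi-square per degree of freedom from 2.53 in dUTP to 466 at 30 pg). Depth set the precision: total counts ran from 9220 to 25531099, and a gene with 0 counts was given a floor of 3 counts over its group, from which the lower bounds of fold changes were computed. Genes with 1 to 3 counts in a group got the ratio of counts per normalized library size with its exact 95% Poisson interval.

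Tests were run in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr by group, glmQLFit and glmQLFTest, Benjamini-Hochberg adjusted p under 0.05). Standard errors were taken from the quasi-likelihood F statistic of each contrast. The 6 libraries of the library preparation groups and the 6 Tn5 libraries were each fitted together, each RNA input was fitted with the 300 ng libraries alone (4 libraries), and the incubations were fitted with temperature and time as additive factors. The design was fixed for 12 incubation libraries and 2 interaction terms. With 10 libraries in the table the additive models were fitted to those 10, and the interaction became 1 term, between 5 and 15 min. The dUTP replicates varied far less than the TABLE-seq replicates, which lowers the shared spread of the library preparation fit, and fits with only 4 libraries or with limma voom and 1 weight per group were run for that reason.

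The genes named were chosen by a rule fixed before the data were examined. For each comparison the rule takes the 5 largest changes each way among genes past the threshold with a mean of at least 10 CPM and every library of 1 group above every library of the other (in the incubations, group means in the same order at every level of the other factor). It adds Pou5f1, Sox2 and Nanog and, for each list that passed camera, the 3 tested members with the highest mean. Where no gene passed, it takes the 3 smallest p-values each way. For the comparison of replicate numbers, added later, it was applied without the condition that every library of 1 group lie above every library of the other. The 14 gene lists (pluripotency, early differentiation, 2-cell-like, fibroblast, replication-dependent histone, cytoplasmic ribosomal protein, mitochondrially encoded, nuclear-encoded respiratory chain, long transcript, small structural RNA, long non-coding RNA, glycolysis, mitosis, immediate early and heat shock) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, where at least 5 members were tested.

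Replicate numbers from the titles were checked for pairing by correlating each library's deviation from its group mean with that of the same-numbered library of another group. In the incubation series the correlation was 0.618 to 0.674 over 10 group pairs (9763 genes), and in the Tn5 series 0.686 to 0.737 over 3 (9730 genes), so the numbers pair those libraries and blocked values are given beside the results. In the library preparation and input series it was -0.00599 to 0.0261 and -0.0278 to 0.0213, and no pairing was assumed.

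Detected genes were counted at 1 and 10 counts, before and after binomial thinning of each library of a series to the smallest total, and related to log10 input with 100000 permutations, 2-sided. Alternatives tried were RLE size factors, DESeq2 1.42.0, no filter beyond 1 count, leaving out each library, the replicate block, thinning, removal of the 10 most abundant genes, other sets of libraries in the fit, and, chosen after the data were seen, voom with group weights, fits within each replicate number and thinning without Rn45s. GC content was not analysed here, since no genome sequence was used. The edgeR step was tested on simulated counts with 200 changed genes. For fragmented TABLE-seq against dUTP it recovered 86.7% of genes changed by 2 on the log2 scale (10212 genes) and at 30 pg against 300 ng 2.78% (4164 genes, 25% of calls false). Of genes changed by 1 it recovered 52.9% for fragmented TABLE-seq against dUTP, 5.95% at 30 ng, 5.38% at 3 ng and 0% at 300 pg. All libraries of a fit were simulated with the same spread, unlike the real dUTP and TABLE-seq replicates. For 37 °C against 16 °C it recovered 45.5% of genes changed by 2 without the block and 93.8% with it (9763 genes), and for 100 against 25 ng Tn5 1.06% and 77.6% (9730 genes). Of genes changed by 1 the same fits recovered 2.11% and 57.7% for temperature and 0% and 37.9% for Tn5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.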

Results

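The series measured RNA of E14 cells, a mouse embryonic stem cell line grown here in serum with leukemia inhibitory factor, by TABLE-seq. In TABLE-seq the transposase Tn5 attaches oligonucleotides to single-stranded DNA or cDNA, which is then ligated to a second adaptor, amplified and sequenced. Libraries made by a dUTP-based protocol, in which dUTP marks 1 cDNA strand of conventional RNA-seq, stood beside them. Counts per gene were analysed for 32 libraries, 2 in each of 16 groups. These were 3 groups that differed in library preparation (dUTP, fragmented TABLE-seq and unfragmented TABLE-seq), 5 RNA inputs (300 ng, 30 ng, 3 ng, 300 pg and 30 pg), 5 incubations (5 and 15 min at 16 °C, and 5, 15 and 30 min at 37 °C) and 3 amounts of Tn5 (25, 50 and 100 ng). The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

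Total counts per library ran from 9220 in replicate 1 of 30 pg to 25531099 in replicate 2 of the dUTP libraries, and the deepest TABLE-seq library held 2916636. Rn45s, the 45S precursor of ribosomal RNA, took most of the counts in many TABLE-seq libraries. Its share was 13.7 ± 0.0508% in the dUTP libraries, 82.4 ± 0.516% with fragmentation and 74.8 ± 6.89% without (mean ± SD, n = 2 each). Along the inputs the share was 81.2 ± 1.30% at 300 ng, 93.7 ± 0.425% at 30 ng, 91.4 ± 0.0369% at 3 ng, 90.6 ± 1.51% at 300 pg and 78.4 ± 4.49% at 30 pg. In the incubation libraries the share split by replicate number, from 66.7% to 70.1% in replicate 1 and from 15.5% to 17% in replicate 2. The Tn5 libraries split in the same way, from 69.1% to 69.6% in replicate 1 and from 18.7% to 20.6% in replicate 2. Outside Rn45s, replicate 1 of those series therefore held 336540 to 603569 counts and replicate 2 held 1227138 to 1802795.

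**Figure D1:**
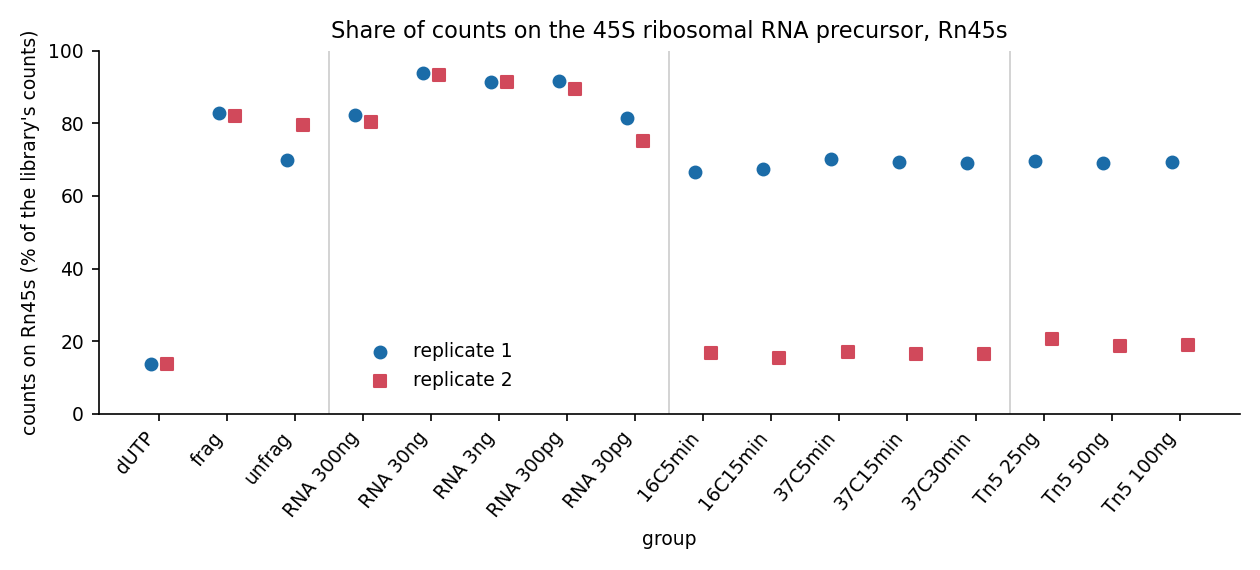
Percent of each library's counts that fell on Rn45s, 1 marker per library (blue circles replicate 1, red squares replicate 2), by group. Replicate 1 of the incubation and Tn5 groups lay between 66.7% and 70.1% and replicate 2 between 15.5% and 20.6%.

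Genes with at least 1 count numbered 17634 ± 45.3 in the dUTP libraries, 10643 ± 486 in fragmented and 12438.5 ± 842 in unfragmented TABLE-seq libraries (mean ± SD, n = 2 each). After every library of this set was thinned to the same total, the means were 13547.5, 10202 and 11619, and after thinning without Rn45s they were 11213.5, 10318.5 and 11133.5. Along the inputs, 11448 ± 133 genes were detected at 300 ng, 9169.5 ± 199 at 30 ng, 7547 ± 103 at 3 ng, 1660 ± 99.0 at 300 pg and 1051.5 ± 624 at 30 pg. Thinned to 1 total without Rn45s, the means were 1245, 903.5, 832.5, 660.5 and 412.5, so fewer genes were found per count outside Rn45s as the input fell. At 30 pg that mean joined 609 and 216 genes in replicates 1 and 2. The 10 most abundant genes took 5.68% to 7.42% of the counts outside Rn45s at 300 ng and 38.3% to 43.7% from 30 ng to 300 pg. Across the 10 input libraries the number thinned without Rn45s, a measure chosen after the data were seen, followed log10 input. Pearson's r was 0.932 and Spearman's rho 0.985 (2-sided permutation test, p = 1e-05 for each, the smallest the test can give, 2e-05 after Benjamini-Hochberg adjustment over 4 relations). Without the 300 ng libraries r was 0.860, and without the 30 pg libraries 0.957. Thinned with Rn45s kept, which was the planned measure, the means were 1279, 345, 436, 414.5 and 441, with no fall below 30 ng. The number then gave r = 0.633 (permutation p = 0.044, adjusted 0.044) and rho = 0.369 (permutation p = 0.30), and r was -0.316 without the 300 ng libraries, on which that relation rests. With at least 10 counts asked for, the thinned libraries held 2 or 3 genes each, apart from 5 and 14 at 30 pg, too few to carry a relation with input (r = -0.593).

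**Figure D2:**
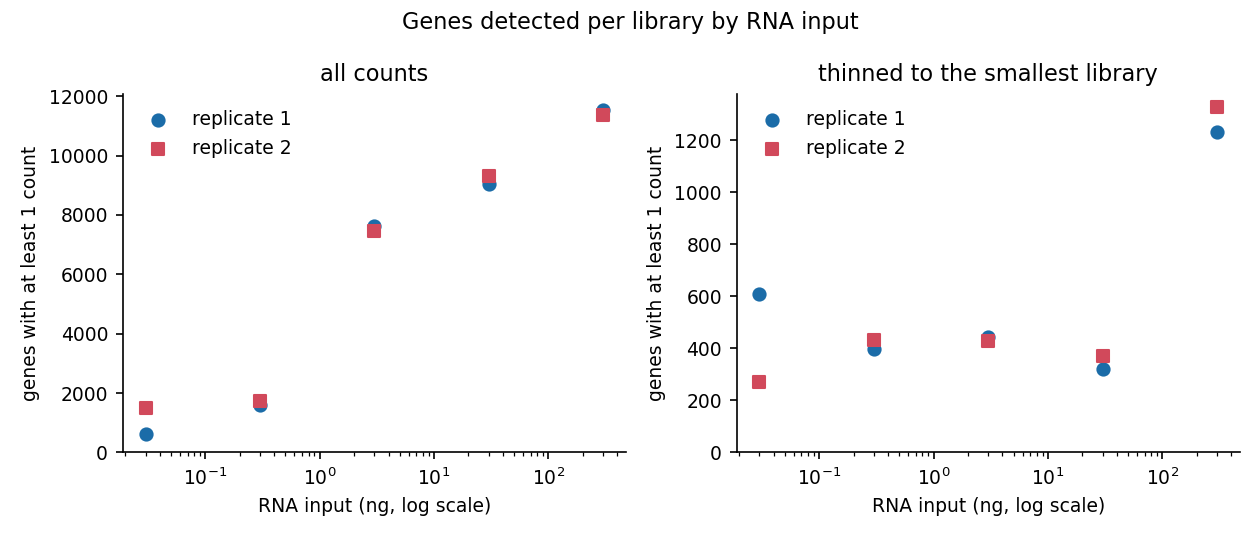
Genes with at least 1 count against RNA input (ng, log axis), from all counts (left) and after thinning to the smallest library with Rn45s kept (right), 1 marker per library (blue circles replicate 1, red squares replicate 2). From all counts the means went from 11448 at 300 ng to 1051.5 at 30 pg.

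Across genes, which are not independent replicates, the correlation of log2(CPM + 1) between the 2 libraries of a group was 0.999 for dUTP, 0.909 for fragmented and 0.938 for unfragmented TABLE-seq. It was 0.899 at 300 ng, 0.850 at 30 ng, 0.727 at 3 ng, 0.306 at 300 pg and 0.0311 at 30 pg. Between methods it was 0.876 for dUTP against fragmented and 0.903 for dUTP against unfragmented libraries. The biological coefficient of variation from edgeR was 0.0316 for dUTP, 0.164 for fragmented and 0.197 for unfragmented libraries. In the incubation groups replicates correlated at 0.865 to 0.877. Libraries of different incubations with the same replicate number correlated at 0.935 to 0.951, each value a mean over replicate numbers 1 and 2. For the Tn5 groups these ranges were 0.850 to 0.873 and 0.946 to 0.956.

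The first comparison set fragmented TABLE-seq beside the dUTP protocol, with log2 fold changes given as the estimate ± its standard error and n = 2 libraries per group throughout. Whether the dUTP and TABLE-seq libraries came from the same cells stays open, as taken up with Hprt at the end. Differences from dUTP, here and for unfragmented libraries, may therefore mix protocol with cells. Long non-coding RNAs were higher in the fragmented TABLE-seq libraries. Neat1, which scaffolds paraspeckles, rose by 4.71 ± 0.15, Malat1, a nuclear speckle RNA, by 2.74 ± 0.21, and Meg3, an imprinted RNA, by 2.65 ± 0.18. The most raised genes were Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123276045 to 123371793, mm9), by 12 ± 0.40, G530011O06Rik by 9.93 ± 0.60, Mir6236 by 9.34 ± 0.39, the Polycomb gene Cbx8 by 8.19 ± 0.82 and Mid1, a microtubule-binding ubiquitin ligase, by 8.08 ± 0.19. Hprt, the purine salvage enzyme (X chromosome, 50341255 to 50374837), had 0 counts against 4972 in the dUTP libraries and was at least 11.3-fold lower. Plagl1, an imprinted zinc finger gene, and Cdx1, a caudal homeobox gene, were also at 0, at least 11.5-fold and at least 11-fold lower. Ftl1, the ferritin light chain, fell by 4.82 ± 0.33, and Mthfd2, a mitochondrial folate enzyme, held 3 counts, a ratio of 13.9 (95% counting interval 4.77 to 67.6). Floors of 3 counts over the group and such intervals cover counting error only. Of the core pluripotency factors, Sox2 rose by 1.07 ± 0.19 (edgeR adjusted p = 0.000266), while Pou5f1 at -0.07 ± 0.21 and Nanog at 0.56 ± 0.21 did not pass (edgeR adjusted p = 0.869 and 0.0675).

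Of 10212 genes tested in this comparison, 1787 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 1077 higher and 710 lower, of which 45 were at 0 counts in fragmented TABLE-seq. Long non-coding RNAs rose in 12 of 17 and fell in 0, as they did adjusted over the list alone (median 1.75, camera adjusted p = 9.69e-13, and adjusted p = 0.0442 with an estimated correlation). Glycolysis genes rose in 0 and fell in 8 of 17 (9 fell adjusted over the list alone, median -0.73, camera adjusted p = 0.000664, but adjusted p = 0.615 with an estimated correlation). Among them Aldoa fell by 0.78 ± 0.22, Pkm by 0.73 ± 0.22 and Hk2 by 0.67 ± 0.23. Replication-dependent histone genes, whose messages lack a poly(A) tail, rose in 22 and fell in 8 of 54 (24 and 8 adjusted over the list alone, median 0.39, camera adjusted p = 0.000921, but adjusted p = 0.800 with an estimated correlation). H1f3 rose by 0.89 ± 0.20, H1f1 fell by 0.79 ± 0.22 and H2bc18 stood at 0.21 ± 0.20 (edgeR adjusted p = 0.505). No other list passed camera. Pluripotency genes rose in 8 and fell in 5 of 26 (9 and 6 adjusted over the list alone, median 0.15, camera adjusted p = 0.228). Early differentiation genes rose in 2 and fell in 1 of 13 (the same adjusted over the list alone, median 0.10, or 0.40 with genes at 0 set to their bound, camera adjusted p = 0.783). Cytoplasmic ribosomal protein genes rose in 15 and fell in 16 of 75 (20 and 19 adjusted over the list alone, median 0.05, camera adjusted p = 0.615). Nuclear-encoded respiratory chain genes rose in 8 and fell in 8 of 69 (9 and 13 adjusted over the list alone, median -0.09, camera adjusted p = 0.889). Long transcripts rose in 7 and fell in 2 of 24 (the same adjusted over the list alone, median 0.07, camera adjusted p = 0.282). Mitosis genes rose in 4 and fell in 1 of 16 (6 and 3 adjusted over the list alone, median 0.02, camera adjusted p = 0.282). Small structural RNAs rose in 5 and fell in 2 of 20 (5 and 3 adjusted over the list alone, median 0.11, or 0.40 at the bound, camera adjusted p = 0.565). Immediate early and heat shock genes rose in 2 and fell in 1 of 11 (2 and 2 adjusted over the list alone, median -0.34, camera adjusted p = 0.936). The single tested 2-cell-like gene rose (also adjusted over the list alone). Fibroblast genes, as markers of another cell type, rose in 0 and fell in 1 of 4 (the same adjusted over the list alone, median -4.71, or -0.10 at the bound), too few for a list test. The list of mitochondrially encoded genes had 0 members in the annotation. The count was 709 without dUTP replicate 1, 690 without dUTP replicate 2, 842 without fragmented replicate 1 and 770 without fragmented replicate 2. It was 2736 (45.7% higher, against 60.3%) with only the 4 libraries in the fit and 454 (45.2% higher) with no filter on low counts. Without dUTP replicate 1 or 2 the calls of Aldoa, Pkm, Hk2, H1f1 and H1f3 were lost (edgeR adjusted p from 0.0807 to 0.299), as were those of Aldoa, Pkm, Hk2 and H1f1 without fragmented replicate 1 (0.0523 to 0.326) and those of Aldoa, Pkm, H1f3 and Cbx8 without fragmented replicate 2 (0.0501 to 0.505). Nanog passed without unfragmented replicate 1 or 2 (edgeR adjusted p = 0.000979 and 0.00067). Cbx8 went to 4.12 without fragmented replicate 2, and Hk2 to -0.37 and -1.26 without fragmented replicates 1 and 2.

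**Figure D3:**
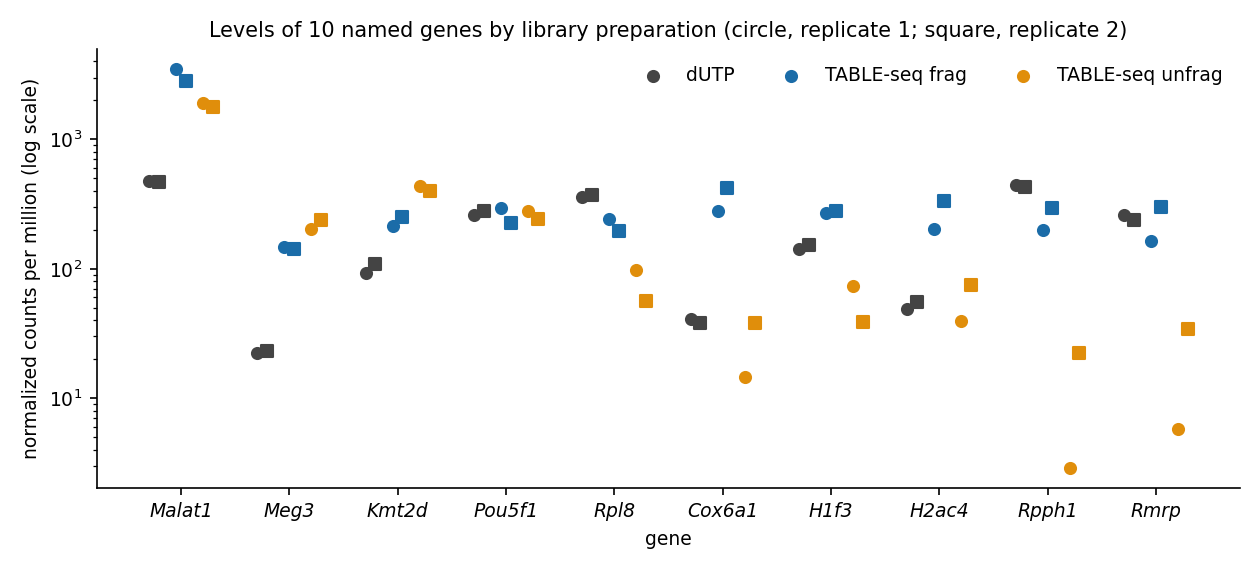
Normalized CPM on a log axis for 10 named genes in the dUTP (grey), fragmented TABLE-seq (blue) and unfragmented TABLE-seq (orange) libraries, 1 marker per library (circles replicate 1, squares replicate 2). Malat1 and Meg3 lay higher in all 4 TABLE-seq libraries than in the dUTP libraries, and Rpph1 and Rmrp lay lowest in the unfragmented ones.

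Unfragmented TABLE-seq was also set beside the dUTP libraries. Of the replication-dependent histone genes, whose list passed camera but not with an estimated correlation (adjusted p = 0.183 with an estimated correlation), H1f1 fell by 3.35 ± 0.26 and H1f3 by 1.45 ± 0.23. Hist1h4m and H4c3, both histone H4 genes, had 0 counts and were at least 34.7-fold and 22.2-fold lower. H4c6, another H4 gene, held 2 counts, a ratio of 66.8 (interval 18.5 to 551), and H3c6 at -0.40 ± 0.19 did not pass (edgeR adjusted p = 0.113). Ribosomal protein genes Rpl8 and Rpl41 fell by 2.3 ± 0.24 and 1.88 ± 0.40, while Rpl4 rose by 0.56 ± 0.20 (0.16 without unfragmented replicate 2). Rpl41 went to -1.17 and -4.11 without unfragmented replicates 1 and 2. Of the respiratory chain, Uqcrc1, a complex III core protein, fell by 1.32 ± 0.20 and Atp5a1, an ATP synthase subunit, by 1.02 ± 0.20. Atp5b stood at -0.42 ± 0.19 (edgeR adjusted p = 0.0990). Of the long transcripts, the histone methyltransferase gene Kmt2d rose by 2.07 ± 0.19, Ahnak by 1.75 ± 0.20 and the ubiquitin ligase Huwe1 by 0.54 ± 0.19.

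Meg3 rose by 3.28 ± 0.12, Neat1 by 3.21 ± 0.16 and Malat1 by 1.97 ± 0.21 in the same comparison. Of the pluripotency genes, L1td1 rose by 1.72 ± 0.23, Tet2 by 1.00 ± 0.19 and Sox2 by 0.78 ± 0.18. Tfcp2l1 stood at 0.10 ± 0.19, Pou5f1 at -0.06 ± 0.20 and Nanog at 0.41 ± 0.20 (edgeR adjusted p = 0.725, 0.857 and 0.123). Of glycolysis genes, Eno1 fell by 0.82 ± 0.21 and Pkm by 0.63 ± 0.21. Aldoa stood at 0.21 ± 0.19 (edgeR adjusted p = 0.411). Gm4832 had 1 dUTP count, a ratio of 12534.5 (interval 2222 to 497742), and Gm20594 had 0, at least 1431-fold higher in unfragmented libraries. Lars2 rose by 10.74 ± 0.38, G530011O06Rik by 10.11 ± 0.42 and Mir6236 by 8.80 ± 0.38. Hprt again had 0 counts, at least 24.3-fold lower, and Rprl3, a copy of the RNase P RNA gene, fell by 5.27 ± 0.36. Without dUTP replicate 1 or 2, Sox2, Pkm, Eno1, Rpl4 and Huwe1 lost their calls (edgeR adjusted p from 0.0755 to 0.442), as did Tet2 without dUTP replicate 1 (0.0503) and Rpl4 without unfragmented replicate 2 (0.511, at 0.16). Pkm went to -0.37 and -0.99 without unfragmented replicates 1 and 2. H3c6 and Atp5b passed without fragmented replicate 1 or 2 (edgeR adjusted p from 0.029 to 0.0456), Atp5b also without unfragmented replicate 1 or 2 (0.0349 and 0.00334), and Nanog without unfragmented replicate 1 (8.32e-05, at 0.62).

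By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3225 of 10212 genes passed between unfragmented TABLE-seq and dUTP, 1739 higher and 1486 lower, 56 of them at 0 counts. Histone genes rose in 1 and fell in 46 of 54 (the same adjusted over the list alone, median -2.39, or -2.36 at the bound, camera adjusted p = 6.78e-35, but adjusted p = 0.183 with an estimated correlation). Respiratory chain genes rose in 2 and fell in 43 of 69 (2 and 45 adjusted over the list alone, median -1.47, camera adjusted p = 1.51e-11, but adjusted p = 0.183 with an estimated correlation). Long non-coding RNAs rose in 12 and fell in 1 of 17 (14 and 1 adjusted over the list alone, median 1.28, camera adjusted p = 1.51e-11, but adjusted p = 0.176 with an estimated correlation). Ribosomal protein genes rose in 9 and fell in 30 of 75 (10 and 32 adjusted over the list alone, median -0.47, camera adjusted p = 4.31e-06, but adjusted p = 0.219 with an estimated correlation). Long transcripts rose in 14 and fell in 2 of 24 (the same adjusted over the list alone, median 0.59, camera adjusted p = 1.72e-05, but adjusted p = 0.316 with an estimated correlation). Pluripotency genes rose in 9 and fell in 2 of 26 (10 and 3 adjusted over the list alone, median 0.13, camera adjusted p = 0.0272, but adjusted p = 0.199 with an estimated correlation). Glycolysis genes rose in 2 and fell in 7 of 17 (3 and 9 adjusted over the list alone, median -0.44, camera adjusted p = 0.0413, but adjusted p = 0.519 with an estimated correlation). Small structural RNAs rose in 2 and fell in 6 of 20 (2 and 8 adjusted over the list alone, median -1.93, or -1.2 at the bound, camera adjusted p = 0.0535). Early differentiation genes rose in 5 and fell in 4 of 13 (5 and 6 adjusted over the list alone, camera adjusted p = 0.938). Mitosis genes rose in 2 and fell in 4 of 16 (the same adjusted over the list alone, camera adjusted p = 0.612). Immediate early and heat shock genes fell in 3 and rose in 0 of 11 (the same adjusted over the list alone, camera adjusted p = 0.133). The 2-cell-like gene rose (also adjusted over the list alone). Fibroblast genes rose in 1 and fell in 1 of 4 (the same adjusted over the list alone). The count was 983 without dUTP replicate 1 and 937 without dUTP replicate 2, and 1849 with no filter on low counts. The share of higher calls, 53.9%, turned to 41.9% with no filter and to 45.1% with only the 4 libraries in the fit.

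Within TABLE-seq, histone, structural RNA, respiratory chain and ribosomal protein genes were among those lower without fragmentation. Their lists passed camera but not with an estimated correlation (adjusted p = 0.113, 0.113, 0.204 and 0.315 with an estimated correlation). H1f3, H2ac4 and H2bc15 fell by 2.34 ± 0.25, 2.18 ± 0.23 and 1.91 ± 0.23, and H2ac20 fell by 5.20 ± 0.61. H4c3 and H2bc14 had 0 counts and were at least 24.3-fold and 17.2-fold lower without fragmentation. The RNA subunits of RNase P and RNase MRP, Rpph1 (chromosome 14, 51427122 to 51427446) and Rmrp, fell by 4.13 ± 0.38 and 3.41 ± 0.38. Without unfragmented replicate 2 they went to a fitted -6.44, with 3 counts left, and to -5.37. The small Cajal body RNA Scarna2 held 1 count, a ratio of 62.2 (interval 10.3 to 2541). Mir6236 stood at -0.53 ± 0.27 (edgeR adjusted p = 0.302). Cox6a1, a cytochrome oxidase subunit, fell by 3.64 ± 0.25. Ndufa1, of complex I, held 2 counts, a ratio of 36.5 (interval 9.35 to 313). Atp5b stood at 0.15 ± 0.21 and Atp5a1 at -0.68 ± 0.23 (edgeR adjusted p = 0.771 and 0.0804). Rpl8 fell by 1.54 ± 0.26, Rpl4 rose by 1.37 ± 0.27 and Rpl41 stood at -1.01 ± 0.46 (edgeR adjusted p = 0.237), or at -3.28 without unfragmented replicate 2. Kmt2d rose by 0.84 ± 0.21. Huwe1 stood at 0.63 ± 0.21 and Ahnak at 0.06 ± 0.22 (edgeR adjusted p = 0.0794 and 0.925). Cspg5, a neural proteoglycan (chromosome 9, 110146287 to 110165080), had 0 counts in fragmented libraries and was at least 7.61-fold higher in unfragmented ones. 9530068E07Rik rose by 4.11 ± 0.53 and Gm4832 by 2.96 ± 0.41. G6pdx, of the pentose phosphate pathway, and Slc52a3, a riboflavin transporter, each held 3 counts in fragmented libraries, ratios of 9.79 (interval 3.20 to 48.7) and 9.48 (interval 3.09 to 47.2). Pou5f1, Sox2 and Nanog stood at 0.01 ± 0.22, -0.28 ± 0.21 and -0.15 ± 0.22 (edgeR adjusted p = 0.988, 0.513 and 0.774).

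Of 10212 genes, 538 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment between the fragmented and unfragmented libraries, 174 higher and 364 lower without fragmentation. Histone genes fell in 41 and rose in 0 of 54 (46 and 0 adjusted over the list alone, median -2.96, or -2.70 at the bound, camera adjusted p = 4.97e-74, but adjusted p = 0.113 with an estimated correlation). Respiratory chain genes fell in 14 and rose in 0 of 69 (30 and 0 adjusted over the list alone, median -1.21, camera adjusted p = 9.61e-14, but adjusted p = 0.204 with an estimated correlation). Ribosomal protein genes fell in 16 and rose in 1 of 75 (17 and 1 adjusted over the list alone, median -0.59, camera adjusted p = 3.59e-07, but adjusted p = 0.315 with an estimated correlation). Small structural RNAs fell in 4 and rose in 0 of 20 (5 and 0 adjusted over the list alone, median -0.92, camera adjusted p = 0.000101, but adjusted p = 0.113 with an estimated correlation). Long transcripts rose in 3 and fell in 0 of 24 (6 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 0.000138, but adjusted p = 0.407 with an estimated correlation). The lists that did not pass camera were pluripotency (2 higher and 2 lower of 26, 4 and 2 adjusted over the list alone, adjusted p = 0.186), long non-coding RNA (2 and 3 of 17, 2 and 5 adjusted over the list alone, 0.469), glycolysis (1 and 0 of 17, 2 and 0 adjusted over the list alone, 0.108), mitosis (0 and 2 of 16, the same adjusted over the list alone, 0.151), immediate early and heat shock (0 and 0 of 11, the same adjusted over the list alone, 0.0777) and early differentiation (0 and 0 of 13, the same adjusted over the list alone, 0.649). Fibroblast genes (0 and 0 of 4, 1 and 0 adjusted over the list alone) and the 2-cell-like gene (0 and 0 of 1) were too few for a list test. Across genes, which are not independent replicates, the change followed exonic length with rho = 0.295, and the median over 5 equal groups of length went from -0.59 through -0.08, 0.12 and 0.21 to 0.30 from the shortest to the longest group. The same rho was 0.336 for unfragmented against dUTP and 0.0308 for fragmented against dUTP. The count was 207 without fragmented replicate 1 and 215 without fragmented replicate 2, 1133 by DESeq2, 158 with limma voom and 1 weight per group, and 0 with no filter on low counts (1824 genes at an unadjusted p under 0.05). Of these calls 15.0% were higher without fragmented replicate 1, 17.7% without fragmented replicate 2 and 14.6% with voom, against 32.3%. Without fragmented replicate 1 or 2 the calls of Cspg5, G6pdx and Slc52a3 were lost (edgeR adjusted p from 0.0903 to 0.2). So were those of G6pdx without unfragmented replicate 2 (edgeR adjusted p = 0.0869), H2bc14 without fragmented replicate 1 (0.135), Rpl4 without fragmented replicate 2 (0.122) and Kmt2d without dUTP replicate 1, dUTP replicate 2 or fragmented replicate 1 (0.0627 to 0.0966). Huwe1 passed without unfragmented replicate 1 or 2 (edgeR adjusted p = 0.00877 and 0.00655), Rpl41 without dUTP replicate 1, dUTP replicate 2 or unfragmented replicate 2 (0.0443, 0.0435 and 5.44e-05), and Atp5a1 and Mir6236 without unfragmented replicate 2 (0.00771 and 0.000384, with Mir6236 at -1.29).

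**Figure D4:**
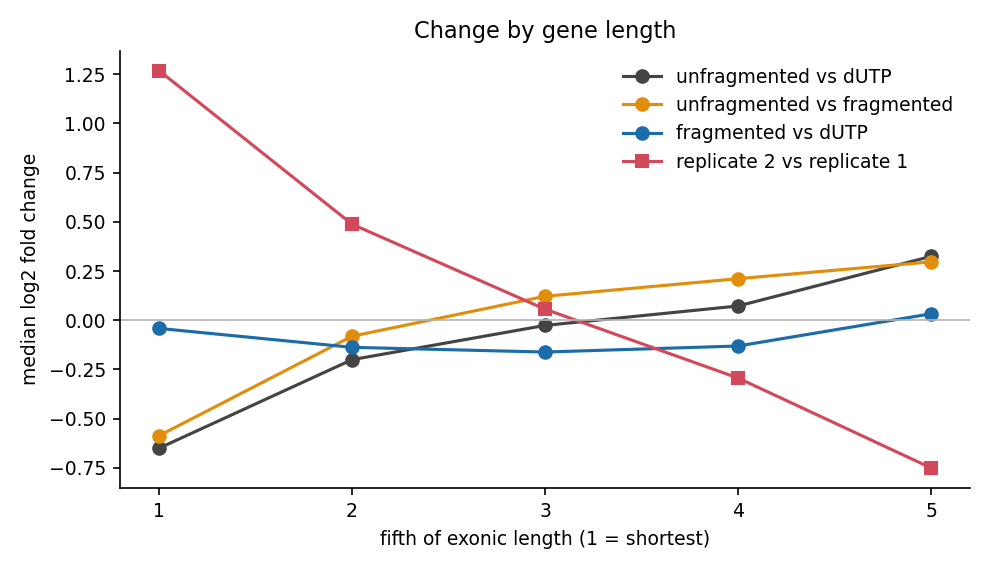
Median log2 fold change over 5 equal groups of exonic length, 1 the shortest, for the 3 comparisons of library preparation (circles) and for replicate 2 minus replicate 1 of the incubation and Tn5 libraries (squares). Unfragmented against fragmented libraries went from -0.59 to 0.30, and replicate 2 minus replicate 1 from 1.27 to -0.75.

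Ribosomal protein, structural RNA, glycolysis and histone genes were among those higher at 30 ng than at 300 ng. Their lists passed camera but not with an estimated correlation (adjusted p = 0.206 with an estimated correlation for each). Rpl41, Rps3 and Rpl8 rose by 3.38 ± 0.26, 3.02 ± 0.23 and 2.24 ± 0.23. Mir6236 rose by 5.66 ± 0.64, Rprl3 by 5.65 ± 0.45, Rpph1 by 4.63 ± 0.23 and Rmrp by 4.51 ± 0.32. The 300 ng libraries differed in 2 of these: Mir6236 went to 9.16 without 300 ng replicate 1 and 4.72 without replicate 2, and all 31 counts of Rprl3 lay in replicate 1, so without it the change rests on 0 counts at 300 ng. Glycolysis genes Aldoa, Pkm and Ldha rose by 2.46 ± 0.28, 1.79 ± 0.22 and 1.37 ± 0.25, and the histone genes H3c6 and H1f1 by 1.85 ± 0.23 and 0.70 ± 0.22. H2bc12 stood at -0.66 ± 0.25 (edgeR adjusted p = 0.0628). Pou5f1 rose by 0.97 ± 0.20 (edgeR adjusted p = 0.000949), while Sox2 at -0.55 ± 0.30 and Nanog at -0.34 ± 0.22 did not pass (edgeR adjusted p = 0.214 and 0.296). Micos10, which shapes mitochondrial cristae, held 1 count at 30 ng, a ratio of 55.4 (interval 9.85 to 2196), and the pseudogene Zfp862-ps 3, a ratio of 20.3 (interval 6.86 to 98.8). Paip2, a regulator of poly(A)-binding protein, fell by 4.07 ± 0.37. Fkbp3, a prolyl isomerase, fell by 3.86 ± 0.61 and Cacybp fell by 3.67 ± 0.33.

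In that comparison 1045 of 6132 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 545 higher and 500 lower at 30 ng. The 30 ng samples were registered apart from those of the other inputs, and the titles do not say whether they were prepared together. An effect of input at 30 ng therefore cannot be told apart from one of a separate preparation. Ribosomal protein genes rose in 28 and fell in 1 of 51 (33 and 1 adjusted over the list alone, median 1.57, camera adjusted p = 1.04e-18, but adjusted p = 0.206 with an estimated correlation). Small structural RNAs rose in 3 and fell in 0 of 5 (the same adjusted over the list alone, median 4.51, camera adjusted p = 2.92e-12, but adjusted p = 0.206 with an estimated correlation). Glycolysis genes rose in 9 and fell in 0 of 17 (the same adjusted over the list alone, median 1.05, camera adjusted p = 1.13e-07, but adjusted p = 0.206 with an estimated correlation). Histone genes rose in 15 and fell in 2 of 41 (16 and 4 adjusted over the list alone, median 0.74, camera adjusted p = 0.000403, but adjusted p = 0.206 with an estimated correlation). The count was 542 without 300 ng replicate 1, 472 without 300 ng replicate 2, 588 without 30 ng replicate 1 and 562 without 30 ng replicate 2. The call of H1f1 was lost without any one of them (edgeR adjusted p from 0.15 to 0.226). DESeq2 called 555, and 1 fit over all 10 input libraries called 188. The share of higher calls was 52.2% in the edgeR fit, 64.5% by DESeq2 and 72.9% in the fit over all inputs. It turned to 33.2% with no filter, 48.1% with the 10 most abundant genes removed and 48.8% without 30 ng replicate 1.

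At 3 ng, structural RNA, ribosomal protein and glycolysis genes were among those higher. Their lists passed camera but not with an estimated correlation (adjusted p = 0.155, 0.155 and 0.157 with an estimated correlation). Rmrp rose by 4.59 ± 0.53, Rpph1 by 3.97 ± 0.22, Rprl3 by 4.81 ± 0.83 (with all 31 of its 300 ng counts in replicate 1) and Rpl37rt by 5.68 ± 0.32. Mir6236 stood at 3.38 ± 1.03 (edgeR adjusted p = 0.115). Rpl41, Rps3 and Rpl8 rose by 3.74 ± 0.36, 2.05 ± 0.25 and 1.48 ± 0.25, and Pkm by 1.36 ± 0.22. Aldoa stood at 1.24 ± 0.42 and Pgam1 at 0.11 ± 0.28 (edgeR adjusted p = 0.132 and 0.843). The pluripotency-associated genes Dppa5a and L1td1 fell by 1.92 ± 0.24 and 1.18 ± 0.19. Pou5f1, Sox2 and Nanog stood at 0.38 ± 0.21, 0.13 ± 0.33 and -0.65 ± 0.23 (edgeR adjusted p = 0.319, 0.841 and 0.141). The most raised genes were H4c6 and the phospholipase gene Plcd1, with 3 counts each at 300 ng and ratios of 72.7 (interval 22.7 to 372) and 68.0 (interval 21.1 to 349). The ornithine aminotransferase gene Oat held 1 count at 3 ng, a ratio of 99.3 (interval 17.8 to 3929). Frg1 and Tmem59 also held 1 count each, ratios of 37.4 (interval 6.65 to 1482) and 31.1 (interval 5.53 to 1235). Cul1, a cullin, and Psmd7, a proteasome subunit, fell by 3.56 ± 0.55 and 3.37 ± 0.56. Psmd7 went to a fitted -6.25 without 3 ng replicate 2, which held 12 of its 13 counts. Gm5662 and Zscan4c, of the 2-cell-like program, had 0 counts at 3 ng, at least 5.59-fold and 3.6-fold lower. Zscan4f held 1, a ratio of 6.25 (interval 1.07 to 253), and none of the 3 passed (edgeR adjusted p = 0.0744, 0.0998 and 0.258).

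Here 122 of 5380 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 71 higher and 51 lower at 3 ng. Small structural RNAs rose in 3 and fell in 0 of 6 (5 and 0 adjusted over the list alone, median 3.68, camera adjusted p = 5.75e-11, but adjusted p = 0.155 with an estimated correlation). Ribosomal protein genes rose in 6 and fell in 0 of 42 (9 and 2 adjusted over the list alone, median 1.20, camera adjusted p = 1.25e-06, but adjusted p = 0.155 with an estimated correlation). Glycolysis genes rose in 2 and fell in 0 of 17 (4 and 0 adjusted over the list alone, median 1.26, camera adjusted p = 5.33e-06, but adjusted p = 0.157 with an estimated correlation). Pluripotency genes rose in 2 and fell in 2 of 25 (5 and 2 adjusted over the list alone, median 0.57, camera adjusted p = 0.0147, but adjusted p = 0.266 with an estimated correlation). Of 5 2-cell-like genes 0 passed (0 higher and 4 lower adjusted over the list alone, median -6.47, or -1.85 at the bound, camera adjusted p = 0.0179, but adjusted p = 0.506 with an estimated correlation). The count was 78 without 300 ng replicate 2, 515 without 3 ng replicate 1 and 621 without 3 ng replicate 2, 189 by DESeq2 and 594 with no filter. The share of higher calls, 58.2%, turned to 37.3% and 37.5% without 3 ng replicates 1 and 2, to 23.1% with no filter and to 41.1% with the 10 most abundant genes removed. Without 300 ng replicate 2 the calls of Frg1, Tmem59 and Cul1 were lost (edgeR adjusted p from 0.061 to 0.188), and that of Tmem59 also without 300 ng replicate 1 (0.0822). Mir6236 passed without any 1 of the 4 libraries (edgeR adjusted p from 5.25e-145 to 0.0479), but its change depended on the library left out. It was 6.95 without 300 ng replicate 1, 2.50 without 300 ng replicate 2, and 3.09 and 3.36 without 3 ng replicates 1 and 2. Aldoa passed without 300 ng replicate 1 (edgeR adjusted p = 0.0137, at 2.04), Gm5662 without 3 ng replicate 1 or 2 (0.0328 and 0.0189) and Zscan4c without 3 ng replicate 2 (0.0453).

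With 300 pg, where the libraries held 112301 and 125941 counts, 2118 of the 4260 tested genes had no count. Rpph1 rose by 3.64 ± 0.61, Rpl37rt by 3.72 ± 0.70, and Syt11, Unc13b and Lamtor1 by 4.63 ± 0.73, 3.63 ± 0.74 and 3.45 ± 0.70. Dppa5a had 0 counts at 300 pg and was at least 29.2-fold lower. The chaperonin gene Cct6a, the helicase gene Dhx15, Psmd7 and the translation factor gene Eif5b were at least 26.3-fold, 14-fold, 11-fold and 8.84-fold lower. Pou5f1, Sox2 and Nanog stood at 1.11 ± 0.49, 0.39 ± 0.57 and -2.09 ± 0.68 (edgeR adjusted p = 0.114, 0.594 and 0.0969). Of the glycolysis list 0 of 13 passed, also adjusted over the list alone (median 0.11, or 0.13 at the bound, camera adjusted p = 0.0243, but adjusted p = 0.522 with an estimated correlation). Pkm stood at 0.24 ± 0.56, Pgam1 at 0.13 ± 0.60 and Aldoa at 0.87 ± 0.82 (edgeR adjusted p = 0.739, 0.868 and 0.391). In all 44 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 14 higher and 30 lower, of which 15 were at 0 counts (bounds of 7.44-fold to 29.2-fold). The median over all tested genes was -4.42 (-0.33 with genes at 0 set to their bound) and -3.96 with RLE size factors, under which 30 genes passed, 76.7% of them higher against 31.8%. That median was -1.96 by DESeq2 and -0.27 after thinning. It was -0.60 and -0.47 without 300 ng replicates 1 and 2, and -6.695 and -6.75 without 300 pg replicates 1 and 2. The count was 2 without 300 ng replicate 1, 2 without 300 ng replicate 2, 659 without 300 pg replicate 1 and 470 without 300 pg replicate 2, and 412 by DESeq2. Each of the calls made without a 300 ng library was higher, against 17.9%, 17.7% and 21.8% in the other 3 fits. Without 300 ng replicate 1 or 2, all 5 named lower genes, Rpl37rt and Rpph1 lost their calls (edgeR adjusted p from 0.0711 to 0.983), as did Rpl37rt and Lamtor1 without 300 pg replicate 2 (0.0676 and 0.345) and Unc13b without 300 pg replicate 1 or 2 (0.125 and 0.124). Nanog passed without 300 pg replicate 1 or 2 (edgeR adjusted p = 0.00221, at -3.83, and 0.048) and Pou5f1 without 300 pg replicate 2 (0.0224). Rpph1 went to 1.91 without 300 pg replicate 1, and Lamtor1 to 2.17 without 300 pg replicate 2.

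With 30 pg, 3090 of 4164 tested genes had no count, and the 2 libraries differed from each other. Replicate 1 held 9220 counts and replicate 2 60615. The 10 most abundant genes took 59.6% of the counts outside Rn45s in replicate 1, led by Lars2 with 462 counts, Tet2 with 261 and Mir6236 with 168. They took 87.2% in replicate 2, led by BC052040 with 3343, Hirip3 with 2385, Scaf1 with 2081 and L1td1 with 1421. Against 300 ng, Eno1b, Canx, Akap12, Nucks1 and Prrc2c had 0 counts and were at least 22.9-fold, 15.1-fold, 14.8-fold, 14-fold and 12.9-fold lower. Pou5f1 held 3 counts, a ratio of 6.01 (interval 2.05 to 29.2), and Nanog 1, a ratio of 21.9 (interval 3.92 to 866). Dppa5a held 1, a ratio of 44.7 (interval 8.02 to 1767), and Sox2 0, at least 2.63-fold lower. The long genes Huwe1 and Usp9x were at 0, at least 10.7-fold and 8.50-fold lower, and Mdn1 held 1 count, a ratio of 17 (interval 3.05 to 674). Rpl32l was at least 2.55-fold lower. Rpl41 stood at 0.38 ± 0.69 (edgeR adjusted p = 0.647) and Rpl4 at 2 counts, a ratio of 2.71 (interval 0.743 to 22.5, edgeR adjusted p = 0.197). Among the higher calls was 0610009B22Rik, with 3 counts and a ratio of 8.95 (interval 1.70 to 30.4). Another was Tet2 at 5.60 ± 2.00 (edgeR adjusted p = 0.0343), with all its counts in replicate 1. L1td1 stood at 4.33 ± 2.89 (edgeR adjusted p = 0.198) with 1421 of its 1422 counts in replicate 2.

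The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 797 genes at 30 pg, 10 higher and 787 lower, of which 639 were at 0 counts and 302 of those at least 2-fold lower at the floor (median bound 1.94-fold). The median over all tested genes was -7.45, or 0.27 with genes at 0 set to their bound. Long transcripts fell in 15 and rose in 0 of 24 (17 and 0 adjusted over the list alone, median -9.01, or -0.95 at the bound, camera adjusted p = 6.12e-06, but adjusted p = 0.663 with an estimated correlation). Pluripotency genes fell in 11 and rose in 1 of 20 (13 and 1 adjusted over the list alone, median -4.17, or -1.95 at the bound, camera adjusted p = 0.0179, but adjusted p = 0.663 with an estimated correlation). Ribosomal protein genes fell in 3 and rose in 0 of 26 (2 and 0 adjusted over the list alone), with a fitted median of -6.89, or 0.37 at the bound, while camera ranked them up (adjusted p = 0.0257, but adjusted p = 0.663 with an estimated correlation). Histone genes fell in 9 and rose in 0 of 31 (10 and 0 adjusted over the list alone, camera adjusted p = 0.137), respiratory chain genes in 3 and 0 of 19 (the same adjusted over the list alone, 0.489) and long non-coding RNAs in 3 and 0 of 10 (4 and 0 adjusted over the list alone, 0.137). Glycolysis genes fell in 4 and rose in 0 of 15 (4 and 1 adjusted over the list alone, camera adjusted p = 0.315) and mitosis genes in 5 and 1 of 16 (7 and 1 adjusted over the list alone, 0.482). Immediate early and heat shock genes fell in 1 of 2 (2 adjusted over the list alone), and 0 passed of 4 early differentiation, 2 2-cell-like, 1 fibroblast and 4 small structural RNA genes. Without 300 ng replicate 1 or without 300 ng replicate 2 the count was 0, without 30 pg replicate 2 it was 47, and it was 500 with RLE size factors and 1917 with no filter. Without 30 pg replicate 2 L1td1 stood at -4.52, and without 30 pg replicate 1 Tet2 stood at -10.23. 0610009B22Rik lost its call without either 30 pg library (edgeR adjusted p = 0.344 and 0.684). The calls of Pou5f1, Sox2, Nanog, Mdn1 and Rpl32l were lost without 30 pg replicate 2 (edgeR adjusted p from 0.141 to 0.589). L1td1 passed upward without 30 pg replicate 1 (edgeR adjusted p = 1.88e-10), and Rpl4, then at 0 counts, passed without 30 pg replicate 1 (0.0311).

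Incubation at 37 °C was set against 16 °C over the 10 incubation libraries. In the fit with the replicate number as a block Cspg5 rose by 3.62 ± 0.27 (edgeR adjusted p = 2.40e-22), with 4.26 within replicate 1 and 3.13 within replicate 2, and Nt5dc2 by 1.78 ± 0.21 (1.69 and 1.80). Sec61g, a subunit of the protein translocation channel, rose by 1.49 ± 0.34 (0.09 and 1.58), Rpl23a by 1.27 ± 0.17 (1.12 and 1.31) and Gm12504 by 1.26 ± 0.31 (2.53 and 1.00). Cox7c, a cytochrome oxidase subunit, fell by 1.69 ± 0.13 (-1.42 and -1.71), H3c11 by 1.75 ± 0.31 (-1.48 and -2.20), Pin1rt1 by 1.61 ± 0.29 (-2.71 and -1.57) and Pdcd5 by 1.83 ± 0.33 (-0.16 and -2.27). Fam25c fell by 1.5 ± 0.17 with 1.2 within replicate 1 and -1.54 within replicate 2, opposite in direction. Without the block edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 9763 genes (231 at an unadjusted p under 0.05, and 1 by DESeq2), and with it 648, 336 higher and 312 lower at 37 °C, of which 33 and 67 lay beyond 2-fold. In the fit without the block the smallest p-values included those of Nt5dc2 at 1.74 ± 0.32, Cspg5 at 4.22 ± 0.85, Gm10653 at 2.95 ± 0.66, Gins4 at -1.23 ± 0.27 and Ebna1bp2 at -1.53 ± 0.34, with edgeR adjusted p = 1.00 for each. With the block Pou5f1, Sox2 and Nanog stood at 0.05 ± 0.09, 0.30 ± 0.10 and 0.22 ± 0.09 (edgeR adjusted p = 0.873, 0.0584 and 0.144).

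By list, with the block, histone genes fell in 6 and rose in 0 of 34 (13 and 0 adjusted over the list alone, median -0.58, camera adjusted p = 1.80e-08, and adjusted p = 0.0112 with an estimated correlation). H2ac4 fell by 0.75 ± 0.19. H3c6 fell by 0.57 ± 0.16, with -0.81 within replicate 1 and 0.34 within replicate 2, and H2bc8 stood at -0.21 ± 0.19 (edgeR adjusted p = 0.640). Without the block 0 of 34 passed (median -0.62, camera adjusted p = 0.0399, but adjusted p = 0.943 with an estimated correlation). Ribosomal protein genes rose in 27 and fell in 5 of 78 with the block (30 and 7 adjusted over the list alone, median 0.23, camera adjusted p = 5.11e-05, but adjusted p = 0.354 with an estimated correlation). Rps3 rose by 0.59 ± 0.11, Rpl41 fell by 0.64 ± 0.12 and Rpl8 stood at 0.10 ± 0.10 (edgeR adjusted p = 0.696). Respiratory chain genes rose in 3 and fell in 11 of 70 (3 and 12 adjusted over the list alone, median -0.19, camera adjusted p = 0.00123, but adjusted p = 0.159 with an estimated correlation). Atp5b, Atp5a1 and Cox6a1 at -0.09 ± 0.09, 0.17 ± 0.10 and -0.16 ± 0.11 did not pass (edgeR adjusted p = 0.692, 0.408 and 0.513). Pluripotency genes rose in 6 and fell in 1 of 26 (11 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 0.0102, but adjusted p = 0.159 with an estimated correlation). The gene that fell was Dppa5a, by 0.85 ± 0.10 (-0.75 and -0.88 within replicates 1 and 2). L1td1 stood at -0.14 ± 0.09 and Tfcp2l1 at 0.21 ± 0.09 (edgeR adjusted p = 0.384 and 0.154). Glycolysis genes rose in 4 and fell in 0 of 17 (6 and 0 adjusted over the list alone, median 0.02, camera adjusted p = 0.0286, but adjusted p = 0.159 with an estimated correlation). Aldoa rose by 0.37 ± 0.10, while Pkm at 0.22 ± 0.09 and Ldha at -0.07 ± 0.11 did not pass (edgeR adjusted p = 0.127 and 0.820). Fitted within a replicate number, the 5 libraries of replicate 1 gave 125 genes (67 higher and 58 lower) and those of replicate 2 gave 602 (297 and 305), fits added after the data were seen. Over 6535 genes tested in both, the changes correlated at 0.350 across genes, which are not independent replicates. Of 124 and 507 genes called there, 68 were called in both, all in the same direction, against 9.62 for independent lists, and 117 of the 124 (94.4%) had the same sign in replicate 2.

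Between 30 and 5 min of incubation Cspg5 rose by 1.89 ± 0.23 in the fit with the replicate block (edgeR adjusted p = 3.32e-09), with 2.67 within replicate 1 and 1.28 within replicate 2, and it was the 1 gene to pass there. Within a replicate number 1 library stood for 30 min, so no count of genes is given for those fits. Without the block edgeR called 0 of 9763 genes (38 at an unadjusted p under 0.05, and 0 by DESeq2). There the smallest p-values belonged to Pgap3 at 2.3 ± 0.80, Pim1 at 0.82 ± 0.30 and Rcbtb2 at 2.06 ± 0.78 upward. Downward they belonged to Gm20605, with 1 count at 30 min and a ratio of 22.8 (interval 3.90 to 921), 4833417C18Rik, with 2 and a ratio of 6.07 (interval 1.51 to 52.9), and Ccdc166, with 0 and at least 3.89-fold lower, and edgeR adjusted p was 1.00 for all 6. With the block Pou5f1, Sox2 and Nanog stood at -0.07 ± 0.12, 0.01 ± 0.13 and 0.03 ± 0.12 (edgeR adjusted p = 1.00 for each). No list passed camera with the block (smallest adjusted p = 0.107). Whether the effect of temperature differed between 5 and 15 min was tested in 1 term, which called 0 genes by edgeR (27 at an unadjusted p under 0.05, and 0 by DESeq2). Among the smallest p-values were those of Sarm1 at 3.23 ± 1.23, Creld1 at 1.86 ± 0.74, Appl2 at -2.80 ± 0.85, Ube2w at -3.13 ± 1.05 and Ptpn9 at -3.79 ± 1.35 (edgeR adjusted p = 1.00 for each). With the block 9530068E07Rik passed at -1.86 ± 0.25 (edgeR adjusted p = 1.44e-07), with -2.95 within replicate 1 and -0.95 within replicate 2. In that fit Pou5f1, Sox2 and Nanog stood at -0.05 ± 0.18, 0.28 ± 0.21 and 0.05 ± 0.18 (edgeR adjusted p = 1.00 for each).

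The amount of Tn5 was compared at 100 and 50 ng against 25 ng. At 100 ng 6 genes passed with the replicate block, all higher, of which Cspg5 rose by 1.93 ± 0.25 (edgeR adjusted p = 1.63e-06), with 1.64 within replicate 1 and 2.13 within replicate 2. The other 5 were Mir6236, up by 0.43 ± 0.06, and 9530068E07Rik by 0.84 ± 0.13, Rpl22 by 0.77 ± 0.17, Rplp1 by 0.62 ± 0.12 and Rpl13a by 0.56 ± 0.12, the last 4 named after their values were seen. At 100 ng without the block edgeR called 0 of 9730 genes (15 at an unadjusted p under 0.05, and 0 by DESeq2). The smallest p-values were those of Vps53 at 2.00 ± 0.61, Ube2j2 at 1.63 ± 0.55, Nars2 at 1.52 ± 0.55, Paox at -2.05 ± 0.71, Fut10 at -2 ± 0.70 and Pnldc1 at -2.02 ± 0.73 (edgeR adjusted p = 1.00 for each). With the block ribosomal protein genes rose in 3 and fell in 0 of 78 (9 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 4.52e-08, but adjusted p = 0.534 with an estimated correlation). Rpl41, Rps3 and Rpl8 stood at 0.11 ± 0.10, 0.18 ± 0.11 and 0.08 ± 0.11. Respiratory chain genes passed camera in that fit with 0 of 71 called (also adjusted over the list alone, median 0.14, adjusted p = 0.0116, with Atp5b, Atp5a1 and Cox6a1 at 0.15 ± 0.10, -0.06 ± 0.11 and 0.21 ± 0.12). So did small structural RNAs with 1 of 22 higher (the same adjusted over the list alone, median 0.14, adjusted p = 0.0116, with Mir682 at 0.12 ± 0.17 and Mir124a-1hg at 0.41 ± 0.46), and both had adjusted p = 0.534 with an estimated correlation. At 50 ng edgeR called 0 genes (8 at an unadjusted p under 0.05, and 0 by DESeq2). The smallest p-values belonged to Vps53 at 2.09 ± 0.60, Ntf5 at 2.53 ± 1.03, Stat5a at 1.89 ± 0.79, Ankrd9 at -2.69 ± 0.89, Gphn at -2.45 ± 0.88 and Nfil3 at -1.88 ± 0.71 (edgeR adjusted p = 1.00 for each). With the block 9530068E07Rik rose by 0.73 ± 0.13 (edgeR adjusted p = 0.00550), also named after its value was seen. In that fit ribosomal protein genes passed camera with 0 of 78 called (3 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.000176, but adjusted p = 0.815 with an estimated correlation). Rpl41, Rps3 and Rpl8 stood at -0.11 ± 0.10, 0.16 ± 0.11 and -0.02 ± 0.11. Without the block no list passed camera (smallest adjusted p = 0.136 at 100 ng and 0.904 at 50 ng). With the block Pou5f1, Sox2 and Nanog stood at 0.11 ± 0.10, -0.07 ± 0.11 and 0.03 ± 0.10 at 100 ng and at 0.16 ± 0.09, -0.06 ± 0.11 and 0.09 ± 0.09 at 50 ng, none past the test (edgeR adjusted p = 1.00 for each).

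The replicate number itself separated the incubation and Tn5 libraries, and it was tested over 8 against 8 libraries with the group as a covariate, a comparison added after the data were seen. Libraries with the same number varied together across groups, so the 8 are not independent replicates of whatever set the numbers apart. The standard errors and p-values here measure only how evenly the difference recurred over the groups. Replication-dependent histone genes were lower in replicate 2, with H3c13, H3c6, H2bc15, H2ac15 and H1f3 at -5.83 ± 0.29, -5.21 ± 0.13, -5.01 ± 0.15, -5 ± 0.31 and -4.92 ± 0.18. Messages of the ribosome and respiratory chain were higher, with Rpl41 up by 3.92 ± 0.10, Rps3 by 3.87 ± 0.09, Cox6a1 by 2.67 ± 0.09 and Ndufa1 by 5.34 ± 0.35. Mir682 rose by 6.32 ± 0.18, Gm15421 by 5.19 ± 0.40, Rpl37rt by 5.05 ± 0.12 and Phpt1, a histidine phosphatase, by 4.95 ± 0.35. Long messages were lower, with Kmt2d falling by 2.85 ± 0.07 and Huwe1 by 1.93 ± 0.07. Pou5f1 rose by 0.50 ± 0.07, and Sox2 and Nanog fell by 0.72 ± 0.07 and 0.20 ± 0.07. Each of these genes moved the same way in 8 of 8 groups. Of 10092 genes 3097 rose and 2737 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Histone genes fell in 37 of 37 (the same adjusted over the list alone, median -3.50, camera adjusted p = 5.85e-40, and adjusted p = 0.00205 with an estimated correlation), and long transcripts in 23 of 24 (the same adjusted over the list alone, median -1.37, camera adjusted p = 4.60e-28, and adjusted p = 0.00119 with an estimated correlation). Ribosomal protein genes rose in 77 of 78 (the same adjusted over the list alone, median 2.26, camera adjusted p = 4.75e-60, and adjusted p = 0.0235 with an estimated correlation), and respiratory chain genes in 71 of 71 (the same adjusted over the list alone, median 2.67, camera adjusted p = 4.39e-31, and adjusted p = 0.0265 with an estimated correlation). Glycolysis genes rose in 11 and fell in 2 of 17 (the same adjusted over the list alone, median 0.42, camera adjusted p = 0.00142, but adjusted p = 0.135 with an estimated correlation). Across genes the change followed exonic length with rho = -0.681, and the median over 5 equal groups of length went from 1.27 through 0.49, 0.06 and -0.29 to -0.75.

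**Figure D5:**
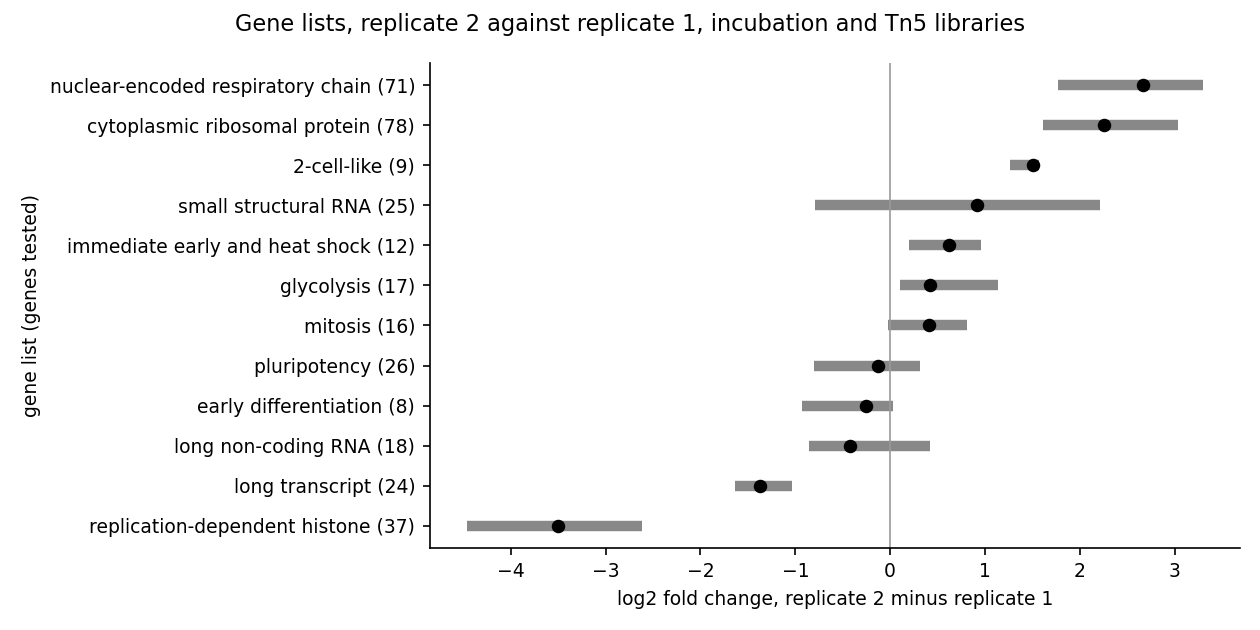
Median log2 change (points) and interquartile range (bars) of each gene list, replicate 2 minus replicate 1, over the 16 incubation and Tn5 libraries, with the number of genes tested in parentheses. Respiratory chain genes had a median of 2.67 and histone genes of -3.50.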

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

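The interaction test was planned without a block, and in that form it called 0 genes. The value given here comes from the same test with the replicate number added as a block, an alternative setting. The effect of temperature on 9530068E07Rik (chromosome 11, 52209930 to 52222225), an uncharacterised gene, differed between 5 and 15 min by -1.86 ± 0.25 on the log2 scale (edgeR adjusted p = 1.44e-07), and that interaction test singled it out. Its normalized CPM in replicates 1 and 2 were 109 and 59.2 after 5 min and 428 and 64.3 after 15 min at 16 °C, and 416 and 128 after 5 min, 211 and 72.0 after 15 min and 684 and 121 after 30 min at 37 °C, in no order of time. The difference was -2.95 within replicate 1 and -0.95 within replicate 2, and without the block the gene was not called.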

How the results depend on the processing

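Fits within replicate numbers, voom with group weights and thinning without Rn45s were chosen after the data were seen, and all other settings were planned. Of 164 recomputed counts of genes, 109 stayed within 1.5 times and 55 moved. Of 2742 values of named genes, 2466 kept their direction and side of the threshold, 193 lost and 81 gained the call, and 2 reversed: L1td1 at 30 pg to -4.52 without 30 pg replicate 2 and Tet2 to -10.23 without 30 pg replicate 1. Each had nearly all its counts in the library left out, and they stood at 6.41 and 6.75 without 300 ng replicate 2. Of 386 list tests 319 kept their call, 55 lost it and 12 gained it. Where a cause is not given the cause was not tested. Depth limits what a count of 0 shows: for the median called gene at 0, the bound was 1.94-fold at 30 pg and 8.16-fold at 300 pg.

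Leaving out 1 library gave 690 to 2367 genes for fragmented against dUTP, 937 to 3480 for unfragmented against dUTP, 207 to 685 for unfragmented against fragmented, 472 to 588 at 30 ng, 78 to 621 at 3 ng, 2 to 659 at 300 pg, 0 to 688 at 30 pg and 0 throughout for the incubation and Tn5 comparisons. A lone library of a group was assumed to vary like the others. DESeq2 gave 1133 for unfragmented against fragmented, 555 at 30 ng, 189 at 3 ng, 412 at 300 pg and 1 for temperature, and RLE size factors 500 at 30 pg. With no filter on low counts, so that more genes were tested, the counts were 454, 1849 and 0 for fragmented against dUTP, unfragmented against dUTP and unfragmented against fragmented, 594 at 3 ng, 675 at 300 pg, 1917 at 30 pg and 2 for temperature. Only 4 libraries in the fit gave 2736 for fragmented against dUTP, voom with group weights 158 for unfragmented against fragmented, and 1 fit over all input libraries 188 at 30 ng, 180 at 300 pg and 152 at 30 pg. Thinning gave 26 at 300 pg and 0 at 30 pg. Detected genes against input gave r = -0.593 with at least 10 counts, where thinning left 2 to 14 genes per library, and the 30 pg replicates correlated at -0.0171 over genes of at least 1 CPM.

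With the replicate block, where the numbers pair the libraries, the counts were 648 for temperature, 1 for time, 1 for the interaction, 6 for 100 ng Tn5 and 1 for 50 ng Tn5. Within replicate 1 and replicate 2 alone, with 1 library per incubation in each fit, temperature gave 125 and 602. In the input series, where they share only a number, the block gave 503 at 30 ng, 308 at 3 ng, 7 at 300 pg and 0 at 30 pg, and it moved no count of the library preparation series by over 1.5 times.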

Other observations

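The comparison of replicate numbers, the tests within replicate numbers, the Hprt count over all libraries, the values of genes across series and the test of histone genes against genes of their length were chosen after the results were seen.

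Cspg5, a proteoglycan gene of neural tissue with 0 counts in the fragmented and 2 in the 300 ng libraries, varied between groups and between replicates. As CPM outside Rn45s, replicates 1 and 2 of Cspg5 held 7.74 and 3.05 after 5 min and 8.63 and 13.7 after 15 min at 16 °C. At 37 °C they held 66.2 and 40.5 after 5 min, 413 and 85.1 after 15 min and 424 and 99.2 after 30 min. With 25, 50 and 100 ng Tn5 they held 59.5 and 23.5, 123 and 52.7, and 193 and 103, and without fragmentation 91.0 and 33.3, against 1.88 and 1.59 in dUTP libraries. 9530068E07Rik held 23.3 and 29 in fragmented, 305 and 784 in unfragmented and 44.4 and 44.9 in dUTP libraries. No test across these series was run.

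Between replicate numbers, where 5834 of 10092 genes were called, 7 lists held called genes without passing camera. Of 9 2-cell-like genes 8 rose and 0 fell in replicate 2 of the incubation and Tn5 libraries (the same adjusted over the list alone, median 1.51, camera adjusted p = 0.103). Immediate early and heat shock genes rose in 6 and fell in 1 of 12 (the same adjusted over the list alone, camera adjusted p = 0.140), and long non-coding RNAs rose in 6 and fell in 8 of 18 (6 and 9 adjusted over the list alone, camera adjusted p = 0.0665). Small structural RNAs rose in 13 and fell in 6 of 25 (the same adjusted over the list alone, median 0.91, camera adjusted p = 0.587). Pluripotency genes rose in 8 and fell in 12 of 26 (the same adjusted over the list alone, camera adjusted p = 0.0834), mitosis genes rose in 8 and fell in 2 of 16 (10 and 2 adjusted over the list alone, camera adjusted p = 0.128), and early differentiation genes fell in 2 of 8 (the same adjusted over the list alone, camera adjusted p = 0.305). Fibroblast genes, too few for a list test, rose in 1 and fell in 1 of 3 (the same adjusted over the list alone).

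Replicates 1 and 2 of the incubation and Tn5 libraries differed in 5834 genes, against at most 2018 in the other flips of the numbers within groups, of which 60 were drawn with the real one included (1 of 60 gave as many). The comparison was chosen after the libraries were seen to split by replicate number. The flips therefore restate that split and are no separate test of chance. A difference in depth is argued against, since 82.4% of these genes stayed called in the same direction after each pair was thinned to the same total without Rn45s. Selection of poly(A) RNA in the replicate 2 libraries is a candidate explanation, since histone genes lay at -3.55 relative to the median of all genes. The share of Rn45s was also lower there, 15.5% to 20.6% against 66.7% to 70.1% in replicate 1. Small structural RNAs rose in 13 and fell in 6 of 25. That list cannot decide, as it takes in microRNA entries such as Mir682 and the host gene Mir124a-1hg. The poly(A) explanation stays open. Better recovery of short transcripts may add to it (rho with exonic length -0.681), but not for the histone genes, which lay at -5.96 relative to the 281 genes of their length. GC content stays open, and no biological explanation was tested, since the labels give none for the replicate number.

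The temperature difference with the block (648 genes) was larger than in the other 80 of 81 splits that kept 2 libraries of each replicate number at 16 °C, with 1 of 81 as large. The highest other count was 132, or 60 among splits that, like the real one, kept the replicates of a group together. Most of the splits parted such replicates and mixed the temperatures, and few kept the groups whole, so they cannot exclude chance. Without the block the real count was 0, which each of the 100 splits drawn from 174 reaches by construction (100 of 100), so that test says nothing about chance. The highest other split, with 2910 genes, set 4 libraries of replicate 1 against the rest, which points to a structure of the samples. Length-related recovery cannot be told apart from an effect on particular genes, since rho with exonic length was 0.185, between the values fixed for and against it. No biological explanation was tested, because all libraries came from 1 cell line and the labels name the incubation only as a library condition.

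Hprt had 4972 counts in the dUTP libraries and 1 count over the 30 TABLE-seq libraries, 29 of which held 0. Depth is argued against, since the dUTP level predicted 2024 counts there. Of 3330 genes within 2-fold of its dUTP level, Hprt was the 1 gene under 1% of its predicted counts, and the median gene had 68.1%. Different cells behind the dUTP and TABLE-seq libraries are a candidate explanation, as the 28 TABLE-seq libraries outside the fragmented ones held 0.0509% of the predicted counts, and some E14 sublines are known to lack functional Hprt. The labels name E14 for both, and a gene-specific loss in TABLE-seq was not tested.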
